A study of Mus musculus with 4 samples.

How the data were processed

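Single-nucleus RNA sequencing libraries of 8 mouse livers were taken from the deposited files. Male and female C57BL/6J mice had been fed standard chow or the FPC diet for 16 weeks, with 2 mice per group of sex and diet and 4 groups. The design text states that the samples of each replicate group were hashtagged and sequenced as 1 pool, so each of the 2 pools held 1 mouse of every group and 4 hashtags, and per the labels 40000 nuclei were loaded per pool. The unit of the deposited matrices is counts: raw UMI counts per gene and nucleus, with antibody counts of the 4 hashtags as the last features of the same matrix. The authors aligned to mm10 with Cell Ranger, version 6.0.1 per the file headers and 3.1 per the submitters' processing notes, and the deposited counts carry no normalization. Barcodes had already been restricted to called nuclei by a caller that is not given in the sources used here, and whether intronic reads were counted is not given there either. The group of each hashtag in each pool came from the sample manifest written by the authors, never from expression. Both pools used the same hashtag for the same group, so a property of a tag cannot be told from a property of its group.

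Hashtags were assigned with HTODemux of Seurat 5.3.0 in R 4.3.3, on counts normalized by centred log ratio across nuclei with a positive quantile of 0.99, and with MULTIseqDemux as an alternative. In pool 2, 9121 barcodes (42.2%) held 1 hashtag, 1923 more than 1 and 10560 none, and in pool 3 10968 (38.4%), 2596 and 15016. Barcodes without a hashtag were shallower, with medians of 2288 and 2184 UMIs against 4683 and 4292.5 for those with 1 hashtag, and barcodes with more than 1 were deeper, with 5685 and 5282. Both callers gave the same group to 99.8% and 99.7% of the nuclei used that both assigned. Nuclei with at least 500 genes and at most 5% mitochondrial counts were kept (19186 and 27148), and Scrublet, through scanpy 1.11.5 in Python 3.11.15, was run per pool with an expected doublet rate of 10% and called 22.0% and 25.3% doublets, which included 44.1% and 45.3% of barcodes with more than 1 hashtag and 20.5% and 24.1% of those with 1. Nuclei with 1 hashtag and no doublet call were used, 6514 and 7890. Xist and the Y-linked genes checked the labels and assigned no nucleus.

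Nuclei were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2) at resolution 0.5, without correction between pools. Cell classes were named from marker lists that were fixed before the data were examined. The numeric naming rules were set after seeing the data. A marker counted for a cluster when it was at least 2-fold over the median cluster after adding 20 CPM and in at least 5% of nuclei. A cluster was hepatocyte-like when under 3 markers of every other class counted and at least 1 hepatocyte marker passed a further rule. That marker had to be in at least 5% of nuclei and at least 1.5-fold over the mean of the clusters that carried 1 other class. The nuclei of all remaining clusters were clustered a second time. There a marker also had to reach at least 0.5 of its level in the highest cluster. A cluster of this second round took the name of the class with the largest share of its markers, at least 3. It stayed unnamed where another class with at least 3 reached over 50% of that share, or where its 10 top genes held no marker of the class or more of another. Nuclei past the filters that were not used took the most frequent class among their 15 nearest used nuclei. Such transferred classes entered the alternatives with Scrublet doublets kept and over all MULTIseqDemux nuclei, and the shares among nuclei without a hashtag. A class is written as, for example, stellate-like, since the name rests on markers.

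Counts were summed per mouse and class, mice being the replicates. Sums were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F tests, two-sided, Benjamini-Hochberg over the genes tested, threshold 0.05) in a model of the 4 groups plus the pool, which left 3 residual degrees of freedom. Contrasts were the diet in females, the diet in males, their average, the sex difference on each diet (female minus male) and the difference of the diet effects (interaction). Fold changes are given as log2 values ± SE, and levels as CPM ± SD over the 2 mice of a group. A mouse needed at least 10 nuclei of a class. Because 2 chow mice held fewer macrophage-like nuclei, a minimum of 5 was used for that class after seeing the data. The rule set before, which asked for 2 mice per group with at least 10 nuclei, would have left the class untested. A fit with the minimum of 10, which left 1 chow mouse of each sex, was added after seeing the data. MULTIseqDemux left 1 chow female for this class, and fits with a lone mouse were allowed there after seeing the data. T or NK cell-like, cholangiocyte-like and mesothelial-like nuclei were too few for gene tests. Sums held 5538701 to 10856744 UMIs in hepatocyte-like, 57710 to 212851 in endothelial-like, 42939 to 141399 in stellate-like and 16920 to 567845 in macrophage-like nuclei, with common biological coefficients of variation of 0.163, 0.108, 0.112 and 0.175.

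The genes named in the text followed a rule set before the data were examined. Among genes past the threshold with a mean of at least 20 CPM and no overlap between the mice of the groups compared, the 6 largest rises and 6 largest falls were named, with up to 2 members of smallest p of each gene list led in that class, and Xist and the Y-linked genes as a check. Genes of the interaction test in stellate-like nuclei, Alb and Hnf4a as measures of free RNA, and Idi1, Nsdhl, Abcc4, Sult2a1 and Krt23 where they stand outside the comparison that named them, were chosen after their values were seen. A gene that the rule chose is not reported here, although counts include it. Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 29 or fewer lists measured, and again with an estimated correlation. Over 168 tests of lists led in their class, 55 passed at the preset correlation, 27 upward and 28 downward, and 1 of them held with an estimated correlation, the female-biased list on chow. Without the pool term 49 of the 55 held and 52 passed.

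Class shares were tested with edgeR on nucleus numbers, adjusted over 7 classes, and the diet effect also by an exact two-sided permutation of the 70 assignments of the diets to the 8 mice, on log2 shares after adding 0.5 nuclei. Intervals of single shares are exact Clopper-Pearson intervals at 95% and cover counting error only. The pairing of mice into pools rests on the design text. As a check, the deviations of the 2 mice of each group from their mean correlated at 0.0885 to 0.255 between groups across 13556 genes, which are not independent replicates.

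The alternatives set before the data were examined were a fit without the pool term, DESeq2 size factors (RLE) in edgeR, the DESeq2 1.42.0 Wald test, no count filter, leaving out each mouse in turn, the MULTIseqDemux assignment, at least 1000 genes per nucleus, Scrublet doublets kept, removal of the 10% of nuclei with the highest doublet scores, sums thinned to the smallest mouse and, for shares, Leiden resolution 1.0, shares among non-hepatocyte nuclei and the permutation, with camera at an estimated correlation for lists and genes of at least 20 CPM for the correlation between the sexes. MULTIseqDemux assignment of all nuclei and removal of nuclei with transcripts of the other sex were added after seeing the data. So were classes from clusters at resolution 1.0, a minimum of 10 macrophage-like nuclei and, for shares, Scrublet doublets kept. The removed nuclei held at least 3 Xist UMIs and no Y-linked UMI in males, or at least 2 Y-linked UMIs and no Xist UMI in females. Nuclei with transcripts of both sexes stayed in. Where a group held 1 mouse, the lone mouse of its group was assumed to vary like the other groups.

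The tests were tested on simulated data with the depth and spread of these sums and 200 changed genes. In hepatocyte-like sums the diet test called 20.9% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 100% of those changed 4-fold; in stellate-like sums the shares were 14.9%, 58.2% and 97.0%, and in endothelial-like sums 23.9%, 71.6% and 100%. Of unchanged genes 4.81%, 5.24% and 5.83% had an unadjusted p under 0.05, and 19, 6 and 10 were called at the adjusted threshold. In hepatocyte-like sums these 19 stood beside 14, 50 and 66 called genes changed 1.5-fold, 2-fold and 4-fold. In endothelial-like sums the 10 stood beside 16, 48 and 66. In both classes false calls were a larger share of all calls in this simulation than the threshold of 0.05 names. Of 32285 genes in the matrices, 32158 were matched to the annotation of GRCm38 (mm10) by Ensembl identifier for coordinates. Other versions were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9 and matplotlib 3.10.9.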

Results

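Nuclei from the top left liver lobe of 8 C57BL/6J mice were profiled by droplet RNA sequencing to compare how livers of females and males differ after a steatohepatitis diet. Mice were fed standard chow or a diet enriched in fructose, palmitate and cholesterol (the FPC diet) for 16 weeks, with 2 mice in each of the 4 groups of sex and diet. The mice were tagged with hashtag antibodies and sequenced in 2 pools, called pool 2 and pool 3 after the labels, each of which held 1 mouse of every group. The files held 21604 barcodes with 92599176 unique molecular identifiers (UMIs) in pool 2 and 28580 barcodes with 110575125 UMIs in pool 3. After filtering, 6514 nuclei of pool 2 and 7890 nuclei of pool 3 carried 1 hashtag and were used. Their totals per mouse, pool 2 before pool 3, were 8285387 and 10946184 UMIs in chow females, 9961116 and 6170287 in FPC females, 6932898 and 10596815 in chow males, and 11331434 and 11085491 in FPC males. FPC mice held more UMIs per nucleus, with medians of 4874 to 5960 UMIs against 3802.5 to 4480 in chow mice. The same hashtag marked the same group in both pools, so the tag and the group cannot be separated.

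Transcripts of the sex chromosomes matched the labels of all 8 mice. Xist, the transcript that silences an X chromosome in females, lay between 2260 and 3160 CPM (counts scaled to the same total in each mouse) in females and between 60.7 and 93.4 in males. Y-linked Uty lay between 7.43 and 20.1 CPM in females and between 259 and 322 in males. Nuclei with transcripts of the other sex and none of the labelled sex made up 0.253% to 3.09% of a mouse's nuclei with transcripts of 1 sex alone. Nuclei with transcripts of both sexes were not counted. Hepatocyte-like nuclei, named by few markers of other classes and by 3 to 5 of Cps1, Hnf4a, Abcb11, Cyp3a25 and Pck1 in each cluster, numbered 12930. The other hepatocyte markers of the list, Alb among them, met the rule in no hepatocyte-like cluster. The other classes held 365 endothelial-like, 321 stellate-like, 242 macrophage-like, 41 T or NK cell-like, 25 cholangiocyte-like and 18 mesothelial-like nuclei. Another 462 nuclei lay in clusters left unnamed. Of these, 50 lay in a cluster with all 9 B cell markers, unnamed by rule because 6 of 8 dendritic cell markers were also high. Unnamed nuclei were at means of 5.43% in chow females, 3.63% in FPC females, 1.96% in chow males and 2.13% in FPC males. Most hepatocyte-like clusters held nuclei of few mice. Cluster 1 held 83.2% and 86.3% of the hepatocyte-like nuclei of the FPC females. Clusters 0 and 3 held 89.1% and 96.8% of those of the chow females of pools 3 and 2. Cluster 4 held 94.8% and cluster 5 held 51.8% of those of the chow males of pools 2 and 3. Clusters 2 and 6 held 97.8% and 63.1% of those of the FPC males of pools 2 and 3. Free hepatocyte RNA was present in all classes. Albumin mRNA (Alb) stood at 19924 CPM in endothelial-like and 19401 CPM in stellate-like nuclei of pool 2 against 10783 CPM in hepatocyte-like nuclei. Hnf4a, a nuclear receptor of hepatocytes, stood at 113 and 83.0 CPM against 353 CPM.

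The first comparison asked which cell classes gained or lost nuclei on the FPC diet. Macrophage-like nuclei rose on the diet, from 0.699% of assigned nuclei in chow mice (± 0.260, SD, n = 4) to 3.15% in FPC mice (± 2.14, SD, n = 4). The log2 change averaged over the sexes was 1.79 ± 0.33 (SE), or 3.46-fold. In females the share rose from 0.760% ± 0.390 to 4.97% ± 0.13 (SD, n = 2 each), a log2 change of 2.61 ± 0.39 or 6.09-fold. In males it was 0.638% ± 0.190 on chow and 1.32% ± 0.587 on the FPC diet, a log2 difference of 0.98 ± 0.53 that did not pass (adjusted p = 0.301). The difference between the sexes in this response was 1.63 ± 0.71 and did not pass either (adjusted p = 0.167). No change passed for hepatocyte-like nuclei (log2 -0.03 ± 0.04, adjusted p = 0.831), endothelial-like nuclei (0.02 ± 0.26, adjusted p = 0.933) or stellate-like nuclei (-0.27 ± 0.25, adjusted p = 0.676). Nor did a change pass for cholangiocyte-like nuclei (-0.51 ± 0.94, adjusted p = 0.831), mesothelial-like nuclei (-2.33 ± 1.66, adjusted p = 0.611) or T or NK cell-like nuclei (0.21 ± 0.70, adjusted p = 0.894). The edgeR adjusted p of the macrophage-like rise was 0.000183 averaged over the sexes and 8.62e-06 in females, two-sided over 7 classes. An exact two-sided permutation of the 70 assignments of the diets to the mice, which held neither sex nor pool fixed, gave p = 0.0571 for the macrophage-like share. The smallest p these assignments can give is 0.0286, too large for a single class to pass over 7 classes. The call averaged over the sexes was lost with clusters at Leiden resolution 1.0 (1.28, adjusted p = 0.0872), over all nuclei assigned by another hashtag caller (1.81, 0.272). It was lost too without the pool 2 FPC female (1.83, 0.215), the pool 3 FPC female (1.88, 0.256) or the pool 2 FPC male (1.49, 0.104). The call in females was lost without either FPC female (2.63 and 2.72, adjusted p = 0.248 and 0.260) and over all nuclei of the other caller (3.04, 0.0814). The male difference passed when Scrublet doublets were kept (1.15, 0.0145). The fall of mesothelial-like nuclei passed without the pool 3 FPC male (-4.81, 0.0136), but this mouse held all 5 such nuclei of the FPC mice.

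**Figure D1:**
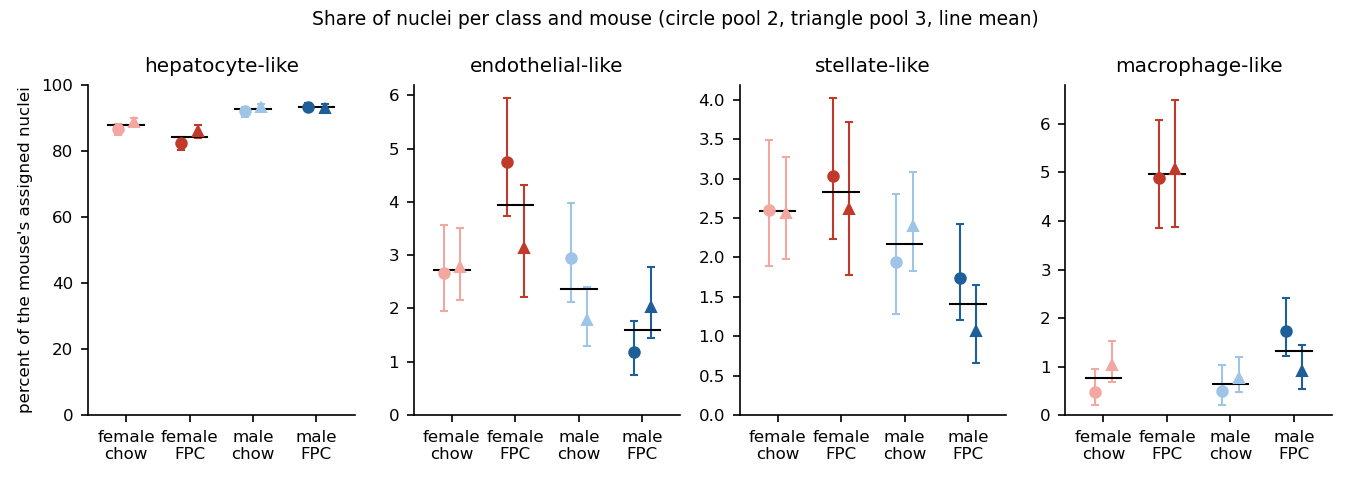
Percent of assigned nuclei in 4 cell classes, 1 symbol per mouse (circle pool 2, triangle pool 3) with 95% exact binomial intervals and a line at the group mean. Macrophage-like nuclei made up 4.88% and 5.07% of the nuclei of the FPC females and at most 1.74% in the other mice.

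Shares also differed between the sexes on the FPC diet, where FPC females held more non-hepatocyte nuclei than FPC males. Macrophage-like nuclei were 3.71-fold higher in females (log2 1.89 ± 0.35, adjusted p = 0.000160). Endothelial-like nuclei were 2.52-fold higher (1.33 ± 0.36, adjusted p = 0.00446; 3.95% ± 1.14 against 1.60% ± 0.605, SD, n = 2) and stellate-like nuclei 2.01-fold (1.01 ± 0.38, adjusted p = 0.0369; 2.83% ± 0.293 against 1.40% ± 0.473). Hepatocyte-like nuclei were lower in females (-0.15 ± 0.06, adjusted p = 0.0408; 84.1% ± 2.54 against 93.1% ± 0.255). On chow no class differed by sex, with a smallest adjusted p of 0.577, and no class passed the test of the difference between the diets. As a share of non-hepatocyte nuclei the 3 differences no longer passed (macrophage-like 0.66, endothelial-like 0.11, stellate-like -0.20). Without the pool 2 or pool 3 FPC female none of the 4 passed (macrophage-like 1.84 and 1.93, endothelial-like 0.96 and 1.58, stellate-like 0.96 and 1.06, hepatocyte-like -0.13 and -0.17). The endothelial-like difference was also lost without the pool 2 FPC male (0.76). The stellate-like difference was lost without either chow female (1.01 both times), either chow male (1.00 both times) or the pool 3 FPC male (0.70), and the hepatocyte-like difference without either chow female or chow male (-0.15 each time). The macrophage-like, stellate-like and hepatocyte-like differences were lost over all nuclei of the other caller (1.79, 1.95 and -0.29). With the other caller applied to the nuclei used, the hepatocyte-like difference alone was lost (-0.16). Nuclei without a hashtag took their class from the nearest nuclei used. By these classes 7.80% of them in pool 2 and 6.87% in pool 3 were endothelial-like, against 2.76% and 2.35% of nuclei with 1 hashtag. Barcodes without a hashtag were also shallower, and an effect of depth on their class was not tested.

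The second comparison asked how the FPC diet changed transcripts of hepatocyte-like nuclei in females. Sult2a1, a sulfotransferase of steroids and bile acids, fell 7.75-fold (-2.95 ± 0.30; chromosome 7, 13796246 to 13837409, GRCm38), from 562 ± 305 to 66.3 ± 4.47 CPM (SD, n = 2 each). Sqle, the squalene epoxidase of cholesterol synthesis, fell 6.52-fold (-2.71 ± 0.24; chromosome 15, 59315077 to 59331192). Themis, best known from T cell development, rose 22.5-fold (4.49 ± 0.31; chromosome 10, 28668360 to 28883818), from 2.53 ± 0.446 to 59.0 ± 39.5 CPM. Osbpl3, an oxysterol-binding protein, rose 14.5-fold (3.85 ± 0.32). The other largest rises were Rbfox1 (3.70 ± 0.52), a splicing regulator, and the transcripts Gm31522, Gm19619 and Gm31333 (2.69 to 3.62). Other large falls were those of Srgap3 (-3.10 ± 0.39), Serpine2 (-2.32 ± 0.45) and Maml3 (-2.27 ± 0.36). In these 11 genes every FPC female lay beyond every chow female, which the naming rule required. With 2 mice per group this held for 7081 of the 13556 genes tested.

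Of 13556 genes tested in hepatocyte-like nuclei, 330 changed in females, 255 higher and 75 lower (edgeR, smallest adjusted p = 0.00256, two-sided), and 3019 had an unadjusted p under 0.05. DESeq2 called 494 genes, 319 higher and 175 lower, the fit without the pool term 192 and that without a count filter 1376. The count was 10 without the pool 2 FPC female, 13 without the pool 3 FPC female, 38 and 77 without the pool 2 and pool 3 chow female, and 536 without the pool 2 FPC male. Of the 28 genes chosen by the naming rule that passed, Themis and Gm31522 were among those that passed under all 20 alternatives. Of the 28, 5 and 6 passed without the pool 2 and pool 3 FPC female, 9 and 12 without the chow females, 23 and 24 without the chow males, and 20 without the pool term.

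Genes of cholesterol synthesis fell together in females, 6 of 25 over all genes tested and 19 when adjusted over the list alone. Sqle, Idi1 (-1.45 ± 0.14), the isopentenyl diphosphate isomerase, and Nsdhl, a sterol dehydrogenase, were among the 6. The list had a median log2 change of -1.22 (camera adjusted p = 5.23e-21, and adjusted p = 0.511 with an estimated correlation). Lipid droplet genes rose, 4 of 18 and 8 when adjusted over the list alone (adjusted p = 5.68e-07, and adjusted p = 0.511 with an estimated correlation). Among them were Plin4, a droplet coat protein (2.24 ± 0.28), and Mogat1, an acyltransferase of triglyceride synthesis (2.60 ± 0.35). Of 29 female-biased liver genes 8 fell, 11 when adjusted over the list alone, where 1 rose (adjusted p = 9.88e-10, and adjusted p = 0.511 with an estimated correlation). Of 23 male-biased genes none passed over all genes, and 5 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00237, and adjusted p = 0.533 with an estimated correlation). Injury and plasticity genes rose, 4 of 11 and 5 when adjusted over the list alone (adjusted p = 1.57e-06, and adjusted p = 0.511 with an estimated correlation), with the stress cytokine Gdf15 (2.34 ± 0.23) and the keratin Krt23 (2.68 ± 0.38). Fatty acid oxidation and PPARA target genes rose in 3 of 25 cases and in 6 when adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.574 with an estimated correlation), with the thiolase Acaa1b (1.37 ± 0.23) and Cyp4a31 (1.39 ± 0.25).

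All 11 mitochondrial transcripts were lower in FPC females when adjusted over the list alone and none over all genes, with a median of -0.62 (adjusted p = 1.63e-06, and adjusted p = 0.533 with an estimated correlation). Free RNA was not removed from the sums. Less of it per nucleus cannot be told apart from lower mitochondrial or secreted transcripts of hepatocytes, here or in males. A lower median and no member past the test over all genes were found for the 15 secreted hepatocyte transcripts, with 0 when adjusted over the list alone (-0.35, adjusted p = 0.00359, and adjusted p = 0.533 with an estimated correlation). The same held for the 15 urea cycle and amino acid genes, with 1 lower when adjusted over the list alone (-0.56, adjusted p = 0.00757, and adjusted p = 0.533 with an estimated correlation). Endoplasmic reticulum stress genes passed as a list, with Gdf15 the 1 of 16 that rose and 2 when adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.533 with an estimated correlation). They did not pass without the pool term (adjusted p = 0.201). The 13 LXR and sterol efflux genes did not pass as a list (adjusted p = 0.0941), although they passed without the pool term. The cholesterol acyltransferase Soat2 (1.30 ± 0.15) and the sterol transporter Abcg8 (1.37 ± 0.27) rose. The 19 lipogenesis genes did not pass (adjusted p = 0.0772; 0.0459 without the pool term, where they passed), nor did any member, with Acaca at -1.01 ± 0.27, adjusted p = 0.0930. Of lists that did not pass as a whole, single members rose. They were Hsd3b7 of bile acid synthesis (0.97 ± 0.15; list adjusted p = 0.494), the interleukin receptor Il1r1 of the acute phase list (0.92 ± 0.16; 0.297). Others were the chemokine Cxcl10 of the NF-kB list (2.27 ± 0.40; 0.297) and Hsd17b6 of the periportal list (0.79 ± 0.13; 0.150). Among NRF2 and xenobiotic genes Aox1 rose (1.00 ± 0.16) and Cyp2b10 fell (-2.41 ± 0.43; list adjusted p = 0.668). Tkfc of fructose metabolism fell (-0.69 ± 0.13; list adjusted p = 0.141).

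In males the question was the same, and the diet raised Ntf3, the growth factor neurotrophin 3, 16.9-fold (4.08 ± 0.16; chromosome 6, 126101412 to 126166910), from 5.00 ± 2.43 to 87.4 ± 51.7 CPM (SD, n = 2 each). Abcc4, an efflux transporter of bile acids and other anions, rose 13.0-fold (3.70 ± 0.30), from 7.57 ± 3.79 to 99 ± 10.7 CPM. Rad51b rose 11.7-fold (3.55 ± 0.27). The leptin receptor Lepr rose 15.0-fold (3.90 ± 0.47; chromosome 4, 101717404 to 101815352), with mice of 1 group far apart (15.6 ± 3.21 CPM on chow and 286 ± 272 CPM on the FPC diet). The largest falls were Srgap3 (-3.84 ± 0.45), Selenbp2 (-3.04 ± 0.38), Sqle (-2.86 ± 0.23), Hsd3b5 (-2.63 ± 0.41), Msmo1 (-2.55 ± 0.33) and Nsdhl (-2.51 ± 0.20). Selenbp2 and Hsd3b5 are higher in male than in female mouse liver, and Sqle, Msmo1 and Nsdhl make cholesterol.

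In males 134 genes changed, 85 higher and 49 lower (edgeR, smallest adjusted p = 0.000100), with 1729 at an unadjusted p under 0.05. DESeq2 called 310 genes, 174 higher and 136 lower, the fit without the pool term 65 and that without a count filter 787. The count was 13 without the pool 2 chow male, 45 without either FPC female and 210 without the pool 3 FPC male. Of the 22 named genes that passed, Ntf3, Abcc4, Rad51b, Gm19619, Srgap3, Sqle and Nsdhl passed under all 20 alternatives. Of the 22, 8 and 10 passed without the pool 2 and pool 3 chow male, 15 and 17 without the FPC males, 9 without either FPC female, 19 and 18 without the chow females, and 11 without the pool term.

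Cholesterol synthesis genes fell in males too, 11 of 25 over all genes and 22 when adjusted over the list alone, with a median of -1.33 (camera adjusted p = 5.81e-50, and adjusted p = 0.444 with an estimated correlation). Male-biased liver genes fell in 4 of 23 cases and in 8 when adjusted over the list alone (adjusted p = 9.35e-11, and adjusted p = 0.444 with an estimated correlation). Serpina1e, a protease inhibitor (-1.18 ± 0.18), fell beside Selenbp2 and Hsd3b5. Lipid droplet genes rose in 3 of 18 cases and in 5 when adjusted over the list alone (adjusted p = 0.000230, and adjusted p = 0.444 with an estimated correlation). Cidea, a protein of droplet fusion (2.94 ± 0.34), and the nuclear receptor Pparg (1.29 ± 0.22) were among them. Urea cycle and amino acid genes had a median of -0.80, with 0 of 15 past the test and 8 lower when adjusted over the list alone (adjusted p = 1.07e-07, and adjusted p = 0.444 with an estimated correlation). Periportal genes had a median of -0.75, with 5 of 12 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.444 with an estimated correlation). The LXR and sterol efflux list passed upward (adjusted p = 0.0279, and adjusted p = 0.444 with an estimated correlation) although its median was -0.02. Abcg1, a sterol efflux transporter, rose (2.46 ± 0.34), and 5 rose and 2 fell when adjusted over the list alone. In the fatty acid oxidation list (adjusted p = 0.00222, and adjusted p = 0.791 with an estimated correlation) the hepatokine Fgf21 was the 1 of 25 that rose (2.52 ± 0.38), with 3 when adjusted over the list alone. Fructose metabolism passed downward without a member past the test (adjusted p = 0.000230, and adjusted p = 0.444 with an estimated correlation; 2 of 17 lower when adjusted over the list alone). So did mitochondrial transcripts (adjusted p = 0.000903, and adjusted p = 0.771 with an estimated correlation) and secreted transcripts (adjusted p = 0.0124, and adjusted p = 0.791 with an estimated correlation), both with 0 when adjusted over the list alone. The acute phase list, with Il1r1 (1.02 ± 0.16), and the NF-kB list, with Icam1 (1.59 ± 0.20), an adhesion molecule, passed upward with 1 riser each (acute phase adjusted p = 0.0144, and adjusted p = 0.791 with an estimated correlation; NF-kB adjusted p = 0.0395, and adjusted p = 0.444 with an estimated correlation). Neither passed without the pool term (adjusted p = 0.0892 and 0.0838). The lipogenesis list did not pass (adjusted p = 0.767), although Pnpla3, a lipid droplet acylhydrolase, rose (2.96 ± 0.47). Neither did the female-biased list (adjusted p = 0.581), in which Acot4 rose (0.97 ± 0.15), nor the pericentral list (0.767), in which Slc13a3 rose (1.51 ± 0.26).

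**Figure D2:**
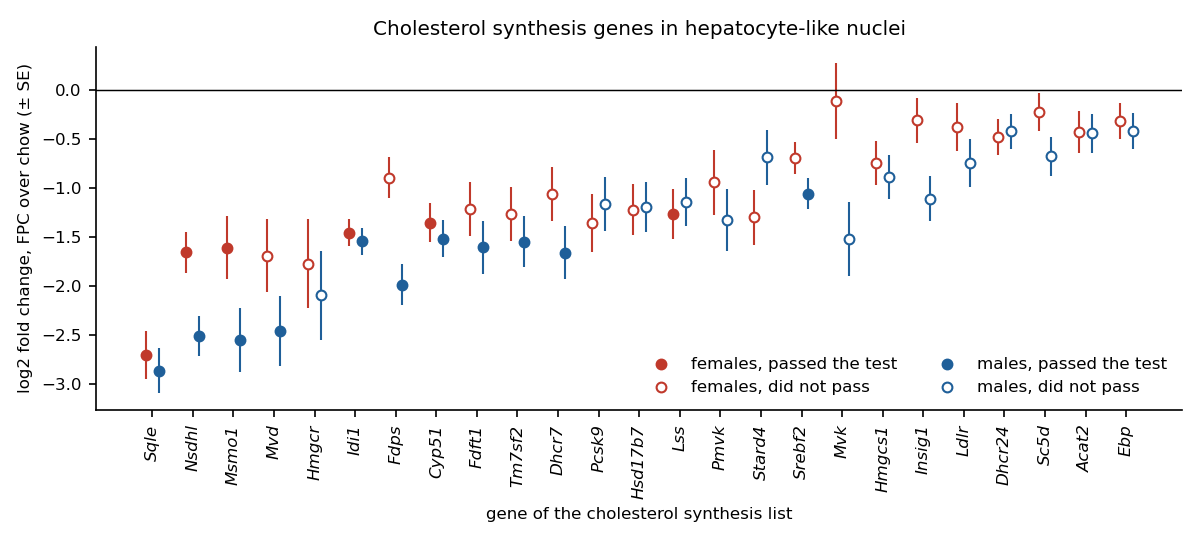
Log2 fold change (FPC minus chow, ± SE) of the 25 cholesterol synthesis genes in hepatocyte-like nuclei of females and males, with filled symbols for genes past the threshold over all genes tested. Sqle fell by 2.71 in females and by 2.86 in males.

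Averaged over the sexes, 435 genes changed, 296 higher and 139 lower (edgeR, smallest adjusted p = 0.000136), with 2886 at an unadjusted p under 0.05. The largest rises were Themis (3.05 ± 0.20), Osbpl3 (2.80 ± 0.21), Gm19619 (2.79 ± 0.15), Rad51b (2.71 ± 0.19), Gm31522 (2.66 ± 0.18) and the cadherin Cdh18 (2.57 ± 0.21). The largest falls were Srgap3 (-3.47 ± 0.29), Sqle (-2.78 ± 0.17), the protocadherin Pcdh11x (-2.76 ± 0.44), Serpine2 (-2.34 ± 0.29), Nsdhl (-2.08 ± 0.15) and Gm36264 (-2.08 ± 0.31). Of 25 cholesterol synthesis genes 18 fell, and 25 when adjusted over the list alone (camera adjusted p = 7.57e-51, and adjusted p = 0.385 with an estimated correlation), with Idi1 at -1.50 ± 0.10. Lipid droplet genes rose in 6 of 18 cases and in 8 when adjusted over the list alone (adjusted p = 2.59e-08, and adjusted p = 0.385 with an estimated correlation), with Plin4 at 1.78 ± 0.19 and Pparg at 1.33 ± 0.15. Urea cycle and amino acid genes fell in 2 of 15 cases, Gls2 (-1.24 ± 0.20), a glutaminase, and Agxt (-0.54 ± 0.10), an aminotransferase. They fell in 11 when adjusted over the list alone (adjusted p = 5.13e-07, and adjusted p = 0.413 with an estimated correlation). LXR and sterol efflux genes rose in 4 of 13 cases and in 5 when adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.385 with an estimated correlation). Soat2 (0.97 ± 0.10) and Abcg8 (1.20 ± 0.19) rose, while the list's median was -0.05. Male-biased genes fell in 6 of 23 cases, Mup7, a major urinary protein, at -0.98 ± 0.13, and in 13 with 1 riser when adjusted over the list alone (adjusted p = 4.38e-09, and adjusted p = 0.385 with an estimated correlation). Female-biased genes fell in 5 of 29 cases with 1 riser, and in 10 with 3 risers when adjusted over the list alone (adjusted p = 0.000246, and adjusted p = 0.385 with an estimated correlation). The NF-kB list did not pass (adjusted p = 0.0553), although Icam1 (1.06 ± 0.14) and Tnfaip3 (1.02 ± 0.21) rose. No interferon gene among 22 passed (list adjusted p = 0.488), with 1 riser when adjusted over the list alone.

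The count averaged over the sexes was 77 and 158 without the pool 2 and pool 3 FPC female, 201 and 197 without the chow females and 167 without the pool 2 chow male, and 1441 without a count filter. DESeq2 called 378 genes higher and 259 lower. Of the 37 named genes that passed, 15 passed under all 20 alternatives, among them Themis, Osbpl3, Sqle, Nsdhl, Idi1, Plin4, Soat2, Abcc4 and Sult2a1. Of the 37, 20 and 26 passed without the pool 2 and pool 3 FPC female, 30 and 27 without the chow females, 34 without either FPC male, 28 and 31 without the chow males, and 27 without the pool term. The endoplasmic reticulum stress list, which passed averaged over the sexes (adjusted p = 0.0199, and adjusted p = 0.580 with an estimated correlation), did not without the pool term (adjusted p = 0.190).

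Changes in females and males could be compared because they share no mice. Across 13556 genes, which are not independent replicates, the log2 changes of the sexes had a Pearson correlation of 0.323 and a Spearman correlation of 0.203. Of all genes 55.3% had the same direction in both sexes. Of the 414 called in either sex, a selected set, 330 (79.7%) did, and 50 were called in both sexes, all with the same direction, where independent calls would give 1.87. Both contrasts use the same estimate of the spread of a gene, so their calls are not independent and 1.87 is no chance level. Sqle, Nsdhl, Srgap3 and Gm19619 were among the 50. The Pearson correlation was 0.202 without the pool 2 FPC female.

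**Figure D3:**
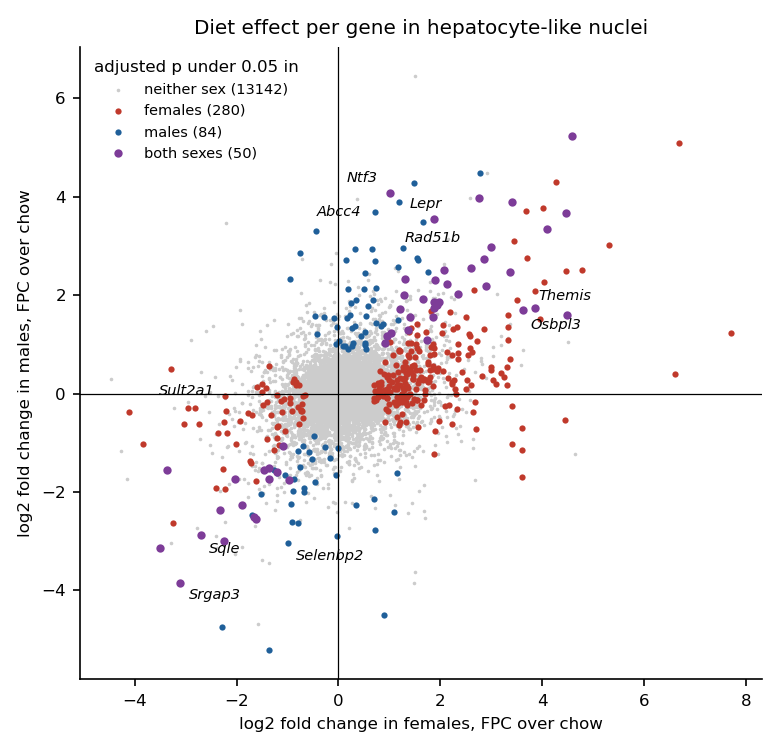
Log2 fold change by diet in females (horizontal axis) against males (vertical axis) of 13556 genes in hepatocyte-like nuclei, coloured by the sex in which the gene was called. Of the genes called, 280 were called in females alone, 84 in males alone and 50 in both.

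The test of a sex difference in the diet response called 1 gene, Ntf3 (female minus male, log2 -3.07 ± 0.21, edgeR adjusted p = 0.00631), which rose by 1.01 ± 0.13 in females and 4.08 ± 0.16 in males. Its levels differed on chow (43.9 ± 21.9 CPM in females, 5.00 ± 2.43 in males, SD) more than on the FPC diet (90.1 ± 50.1 and 87.4 ± 51.7). Abcc4 (-2.98 ± 0.39, adjusted p = 0.0904), Sult2a1 (-2.67 ± 0.41, adjusted p = 0.129) and Krt23 (2.85 ± 0.63, adjusted p = 0.187) did not pass, so the calls made in 1 sex alone were not shown to differ between the sexes. As lists, female-biased genes had a median of -0.89 with 8 lower and 1 higher when adjusted over the list alone (adjusted p = 9.97e-10, and adjusted p = 0.788 with an estimated correlation). Injury and plasticity genes had a median of 0.53 with 4 higher when adjusted over the list alone (adjusted p = 0.00496, and adjusted p = 0.788 with an estimated correlation). Acute phase genes had a median of -0.36 with 0 (adjusted p = 0.0124, and adjusted p = 0.788 with an estimated correlation; 0.0977 without the pool term). At an unadjusted p under 0.05 there were 1841 genes, DESeq2 called 105, the fit without a count filter 511, that with Scrublet doublets kept 3 and that over all nuclei of the other caller 2. The call of Ntf3 was lost without the pool term, either FPC female, the pool 3 chow female or the pool 2 chow male (0 genes called each time, with 1244 to 1580 at an unadjusted p under 0.05). Without the pool 3 FPC male and the pool 3 chow male 11 and 2 genes were called.

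Sex differences on each diet were compared next, as female minus male. On chow, hepatocyte-like nuclei of females held more Cux2, a transcription factor (529 ± 337 against 13.2 ± 6.79 CPM, SD, n = 2; log2 5.30 ± 0.75), Setbp1 (4.24 ± 0.23), the sulfotransferases Sult2a3 (4.58 ± 0.71) and Sult2a1 (4.22 ± 0.32), and Xist (4.90 ± 0.27). Males held more Scara5, a ferritin receptor (-4.63 ± 0.31), Susd4 (-4.26 ± 0.45), Zfp992 (-4.20 ± 0.30), Gm50136 (-4.58 ± 0.27) and the Y-linked Kdm5d (-4.38 ± 0.21) and Uty (-4.31 ± 0.27). Of 29 female-biased liver genes 17 were higher in females, and 29 when adjusted over the list alone, with a median of 3.07 (camera adjusted p = 1.56e-100, and adjusted p = 0.0173 with an estimated correlation). Cyp2b13, a cytochrome P450, was at 3.82 ± 0.22. Of 23 male-biased genes 12 were lower in females, and 19 when adjusted over the list alone (adjusted p = 2.54e-41, and adjusted p = 0.168 with an estimated correlation). Complement component C6 was at -3.86 ± 0.23 (chromosome 15, 4727175 to 4814967). Slco1a1, an uptake transporter of organic anions, was lower in females (-3.52 ± 0.37), and Abcc4 higher (2.77 ± 0.30). The 4 Y-linked genes, Xist and Tsix passed as a list (adjusted p = 1.37e-12, and adjusted p = 0.168 with an estimated correlation). So did cholesterol synthesis, lower in females (adjusted p = 0.0279, and adjusted p = 0.800 with an estimated correlation) with Fdps the 1 of 25 that passed (-1.07 ± 0.20). The 4 genes that escape X inactivation did not pass (adjusted p = 0.0592; 0.0415 without the pool term, where they passed), with 2 higher when adjusted over the list alone. In all, 203 genes differed on chow, 105 higher and 98 lower in females (edgeR, smallest adjusted p = 0.000193; 1598 at an unadjusted p under 0.05), and 345 by DESeq2 and 679 without a count filter. The count was 67 without the pool 3 chow female, 75 and 109 without the chow males, and 124 and 125 without the FPC females. Of the named genes, 16 of the 21 named genes that passed did so under all 20 alternatives, Cux2, Sult2a3, Susd4, Il1r1 and Fdps being the others.

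On the FPC diet 759 genes differed by sex, 452 higher and 307 lower in females (edgeR, smallest adjusted p = 9.51e-05; 3420 at an unadjusted p under 0.05). Cyp2b13 was 30.4-fold higher in females (4.93 ± 0.23; 677 ± 210 against 21.9 ± 0.767 CPM, SD, n = 2; chromosome 7, 26061497 to 26096197). Setbp1 (4.71 ± 0.24), Sult2a3 (3.79 ± 0.71), Cux2 (3.76 ± 0.69), Xist (5.51 ± 0.28) and its antisense transcript Tsix (5.64 ± 0.27) were the other largest differences upward. Zfp992 (-4.79 ± 0.31), the transporter Slc22a28 (-4.27 ± 0.44), Scara5 (-4.10 ± 0.37) and the Y-linked Uty, Kdm5d and Eif2s3y (-5.35 to -4.18) were the largest downward. Female-biased genes were higher in 17 of 29 cases and in 24 when adjusted over the list alone (adjusted p = 4.69e-26, and adjusted p = 0.178 with an estimated correlation). Male-biased genes were lower in 9 of 23 and in 14 when adjusted over the list alone (adjusted p = 4.62e-17, and adjusted p = 0.428 with an estimated correlation), with C6 at -4.05 ± 0.24 and Cyp4a12a at -3.38 ± 0.30. Injury and plasticity genes were higher in 3 of 11 cases and in 7 when adjusted over the list alone (adjusted p = 0.000166, and adjusted p = 0.428 with an estimated correlation), with Krt23 at 2.94 ± 0.37 and Gdf15 at 1.64 ± 0.21. Urea cycle and amino acid genes passed upward with Hal, the histidine ammonia-lyase, the 1 of 15 that passed (1.24 ± 0.28; list adjusted p = 0.0107, and adjusted p = 0.993 with an estimated correlation). Lipid droplet genes moved both ways, with Mogat1 higher (1.76 ± 0.30) and Cidea lower (-2.85 ± 0.34) in females (list adjusted p = 0.991). Higher in females were Akr1d1 of bile acid synthesis (1.24 ± 0.19), the cholesterol exporter Npc1 (1.06 ± 0.18) and the acyltransferase Dgat2 (1.02 ± 0.17). Lower were Slco1a1 (-2.74 ± 0.36), Steap4 (-1.72 ± 0.22) and Il1r1 (-1.04 ± 0.16). Among cell cycle genes Kif15, a mitotic kinesin near the detection floor at 0.25 CPM in FPC females and 2.06 CPM in FPC males, was lower in females (-2.85 ± 0.62; list adjusted p = 0.376).

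The sex differences of the chow mice and of the FPC mice share no mice, and 117 genes passed in both, 116 with the same direction, where independent calls would give 5.72. They do share the estimate of the spread of each gene, so 5.72 is no chance level. The count on the FPC diet was 48 and 44 without the pool 2 and pool 3 FPC female, 285 without the pool 3 FPC male, 466 without the pool term and 1895 without a count filter. Of the 34 named genes that passed on the FPC diet, 12 passed under all 20 alternatives, among them Cyp2b13, Setbp1, C6, Cyp4a12a, Slc22a26 and Zfp992. Of the 34, 12 and 14 passed without the pool 2 and pool 3 FPC female, 26 and 22 without the FPC males, and 27 without the pool term.

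**Figure D4:**
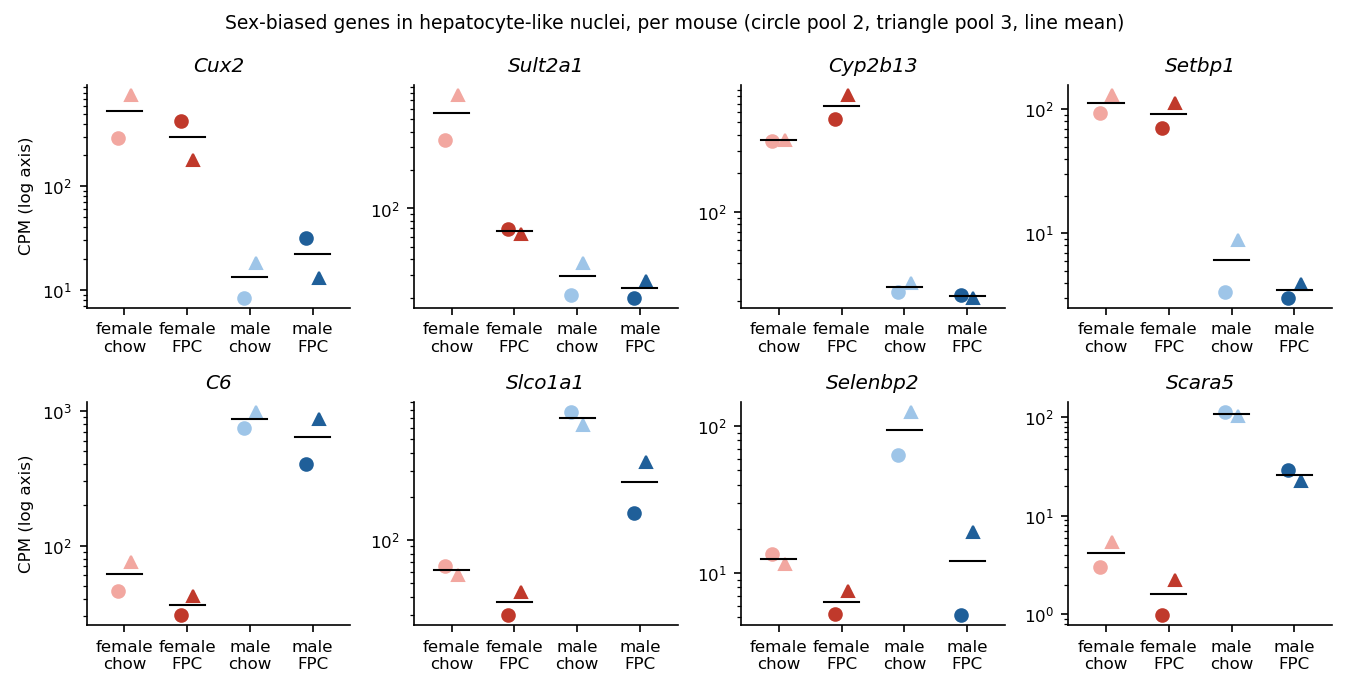
CPM per mouse (log axis) of 8 sex-biased genes in hepatocyte-like nuclei of the 4 groups, 1 symbol per mouse. Cux2 averaged 529 CPM in chow females and 13.2 CPM in chow males.

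In stellate-like nuclei, the comparison asked whether genes of the matrix-producing cells of the liver changed with the diet. Averaged over the sexes the fibrillar collagen Col3a1 rose 2.34-fold (1.23 ± 0.27; chromosome 1, 45311538 to 45349706), Ecm1, a matrix protein, rose 2.02-fold (1.01 ± 0.23) and Col14a1 rose 1.84-fold (0.88 ± 0.16; n = 4 mice per diet). Dcn, the proteoglycan decorin (0.77 ± 0.13), and Colec11, a collectin (0.99 ± 0.25), rose as well. Cmah (-1.51 ± 0.38), Prr16 (-1.21 ± 0.29) and Errfi1 (-0.67 ± 0.19) fell. Of the extracellular matrix list 2 of 14 measured genes rose, and 5 when adjusted over the list alone (median 0.67, camera adjusted p = 3.96e-09, and adjusted p = 0.143 with an estimated correlation). Of the stellate cell list 2 of 8 rose, and 3 when adjusted over the list alone (median 0.39, adjusted p = 8.00e-05, and adjusted p = 0.273 with an estimated correlation). In females the matrix list rose with 5 of 14 genes, and 10 when adjusted over the list alone (median 1.12, adjusted p = 2.20e-12, and adjusted p = 0.0912 with an estimated correlation), and in males it had a median of 0.11 and did not pass (adjusted p = 0.214). The test of the sex difference gave a median of 0.83 for the matrix list, with 3 higher when adjusted over the list alone (adjusted p = 0.00609, and adjusted p = 0.323 with an estimated correlation), and 0.38 for the stellate cell list (adjusted p = 0.0354, and adjusted p = 0.454 with an estimated correlation; 0.166 without the pool term). Of 2472 genes tested on sums of 42939 to 141399 UMIs, 18 changed, 12 higher and 6 lower (edgeR, smallest adjusted p = 3.07e-05; 219 at an unadjusted p under 0.05).

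No gene of stellate-like nuclei passed without the pool term (edgeR; 152 at an unadjusted p under 0.05), 1 passed by DESeq2, 4 without a count filter, 8 with clusters at resolution 1.0 and 9 with the MULTIseqDemux assignment. The count was 9 and 10 without the FPC females, 5 without the pool 3 FPC male, and 11 and 7 without the pool 2 and pool 3 chow male. Without these mice 3 to 6 of the 8 named genes still passed, and 3 without the pool 3 chow female. None of the 8 passed among the 27 genes called with Scrublet doublets kept, Dcn being lost in 2 and Col14a1 in 3 of all 20 alternatives and Col3a1 in 9 of 20. The call of Ecm1 was lost in 9 of 20 and that of Colec11 in 12. The 3 falls were lost in most alternatives, Prr16 in 12 of 20, Errfi1 in 15 of 20 and Cmah in 15 of 19.

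**Figure D5:**
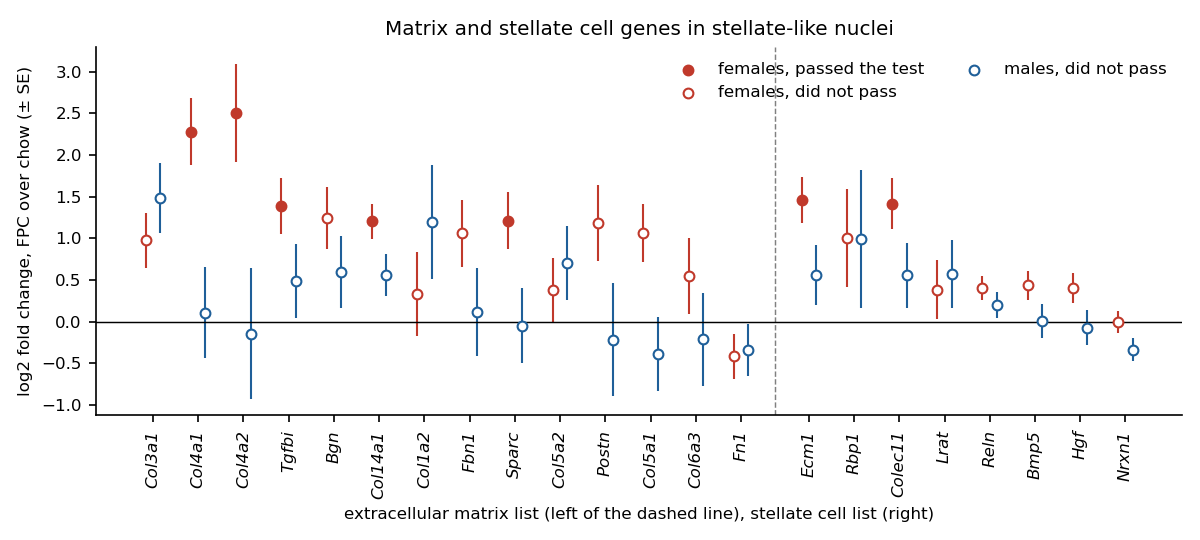
Log2 fold change (FPC minus chow, ± SE) in stellate-like nuclei of females and males for 14 extracellular matrix genes and 8 stellate cell genes. Median changes of the matrix genes were 1.12 in females and 0.11 in males.

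In endothelial-like nuclei, 2 of 2515 genes passed averaged over the sexes, both higher on the FPC diet (edgeR; 165 at an unadjusted p under 0.05), on sums of 57710 to 212851 UMIs. Cd5l, a protein that macrophages secrete, rose 5.73-fold (2.52 ± 0.47, adjusted p = 0.0342), from 30.1 ± 2.32 to 186 ± 8.16 CPM in females and from 31.9 ± 1.86 to 190 ± 25.4 CPM in males (SD, n = 2 each). Tmsb4x, the actin-binding thymosin beta 4, rose 2.19-fold (1.13 ± 0.17, adjusted p = 0.00495). None of the 11 sinusoidal identity genes passed (median 0.06, list adjusted p = 0.807), with coagulation factor F8 at 0.26 ± 0.14, adjusted p = 0.751 and Gata4 at -0.23 ± 0.18, adjusted p = 0.858. The call of Cd5l was lost in 12 of 19 alternatives, with log2 changes between 1.17 and 2.62, and that of Tmsb4x in 3 of 20. The count was 1 by DESeq2 and in thinned sums, 6 with Scrublet doublets kept, 7 with the MULTIseqDemux assignment, 0 without the pool 2 chow female, the pool 3 FPC male or the pool 3 chow male (edgeR; 165, 174 and 143 at an unadjusted p under 0.05), and 1 without the pool 2 FPC female, the pool 2 FPC male or the pool 2 chow male.

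In macrophage-like nuclei, tested with at least 5 nuclei per mouse, Ldb2, a LIM domain-binding protein, rose 6.83-fold (2.77 ± 0.42), Zbtb46, a zinc finger factor of dendritic and endothelial cells, rose 7.40-fold (2.89 ± 0.65), and Rad51b rose 7.24-fold (2.86 ± 0.52; n = 4 mice per diet). Lama4, a laminin chain (adjusted p = 0.00233), Tnik (0.00233) and Csmd1 (0.0115) also rose. Lama4 went from 66.1 to 263 CPM in females and from 0 to 269 CPM in males, Tnik from 83.5 to 200 and from 0 to 370 CPM, and Csmd1 from 26.0 to 169 and from 0 to 197 CPM. Falls were found in Cyp2c50 (-1.24 ± 0.34), Apoc4 (-1.02 ± 0.25), Mgst1 (-0.98 ± 0.22), Cyp3a11 (-0.95 ± 0.22) and Dbi (-0.92 ± 0.24), which hepatocytes express. None of the 5 measured lipid-associated macrophage genes passed (median 0.27, list adjusted p = 0.451), the fatty acid transporter Cd36 being at 0.81 ± 0.38, adjusted p = 0.294, and none of the 7 measured Kupffer cell genes (median -0.03, list adjusted p = 0.384), Cd163, a scavenger receptor, being at -0.80 ± 0.31, adjusted p = 0.164. Beside these changes, 11 of 15 secreted hepatocyte transcripts fell in the class, 14 when adjusted over the list alone (median -0.75, adjusted p = 1.06e-19, and adjusted p = 0.245 with an estimated correlation), and 2 of 8 sinusoidal endothelial genes rose, 4 when adjusted over the list alone (median 1.31, adjusted p = 0.000107, and adjusted p = 0.245 with an estimated correlation).

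Of 2454 genes, 81 changed in macrophage-like nuclei, 45 higher and 36 lower (edgeR, smallest adjusted p = 9.71e-05; 370 at an unadjusted p under 0.05; 60 by DESeq2), on sums that ran from 16920 to 567845 UMIs. None of 552 genes tested passed with clusters at resolution 1.0 (edgeR; 36 at an unadjusted p under 0.05), and the count was 14 without the pool term, 30 without nuclei that held transcripts of the other sex, 39 with at least 1000 genes per nucleus, 45 with Scrublet doublets kept, 48 after stricter doublet removal and 46 of 351 genes tested in thinned sums. It was 50 with the MULTIseqDemux assignment, 21 with that of all nuclei and 38 with at least 10 nuclei per mouse. Without single mice it was 40 (pool 2 FPC female), 147 (pool 3 chow female), 39 and 24 (pool 2 and pool 3 FPC male), and 44 and 37 (pool 2 and pool 3 chow male). Of the 11 named genes that passed, Ldb2 and Rad51b passed under every alternative that gave them a value, with log2 changes from 1.34 to 5.44 and from 2.25 to 5.34. The other rises were lost in 2 of 19 (Lama4), 3 of 18 (Tnik), 5 of 18 (Csmd1) and 6 of 19 alternatives (Zbtb46). The falls were lost more often, in 16 of 21 (Apoc4), 16 of 19 (Cyp2c50), 12 of 21 (Dbi) and 7 of 21 alternatives (Mgst1 and Cyp3a11).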

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

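Of the tests below, those of male nuclei, of free RNA and over all nuclei of the other caller were chosen only after the result was seen, and the test of depth was set before.

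Results in this part stood out because a test of the difference between the sexes passed, or because nuclei outside the reported comparisons held a signal. In hepatocyte-like nuclei the diet response of Ntf3 was lower in females by a log2 value of -3.07 ± 0.21 (edgeR adjusted p = 0.00631, 0.300 without the pool term, 7.22e-16 by DESeq2), and the call ended without the pool 3 chow female (-2.95), the pool 2 or pool 3 FPC female (-3.10 and -3.05) or the pool 2 chow male (-2.99). Mean levels on the FPC diet were 90.1 CPM in females and 87.4 CPM in males, against 43.9 and 5.00 CPM on chow. In stellate-like nuclei 7 of 2472 genes passed that test: Lsamp at 2.12 ± 0.30 (adjusted p = 4.01e-08), Kcnq5 at 2.11 ± 0.38 (7.12e-05), Adamts9 at 1.95 ± 0.50 (0.0453), Nhsl2 at 3.97 ± 0.96 (0.0236), Nkain2 at 1.09 ± 0.26 (0.0236), Zfp804b at 1.18 ± 0.30 (0.0376) and Ptprt at -2.07 ± 0.47 (0.0131). Without the pool term Lsamp alone still passed (0.0475, the others 0.0640 to 0.758), and by DESeq2 none did (adjusted p of 0.285 to 1.000).

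As lists, the diet response of female-biased liver genes was lower in females than in males, with a median of -0.89 (adjusted p = 9.97e-10, and adjusted p = 0.788 with an estimated correlation), as was that of acute phase genes (-0.36, adjusted p = 0.0124, and adjusted p = 0.788 with an estimated correlation). The response was higher in females for injury and plasticity genes (0.53, adjusted p = 0.00496, and adjusted p = 0.788 with an estimated correlation) and, in stellate-like nuclei, for extracellular matrix genes (0.83, adjusted p = 0.00609, and adjusted p = 0.323 with an estimated correlation) and stellate cell genes (0.38, adjusted p = 0.0354, and adjusted p = 0.454 with an estimated correlation).

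By classes taken from their nearest used nuclei, nuclei that HTODemux left without a hashtag held larger shares of non-parenchymal nuclei than nuclei with 1 hashtag. An effect of their lower depth on these classes was not tested. These untagged nuclei entered only the alternative over all MULTIseqDemux nuclei. In pools 2 and 3, 7.80% and 6.87% of them were endothelial-like (2.76% and 2.35% with 1 hashtag), 9.82% and 7.48% stellate-like (2.30% and 2.17%) and 4.16% and 3.46% macrophage-like (1.89% and 1.51%). No mouse stood apart from the others of its diet in the 20 groups of 4 mice and measures looked at, where chance would mark about 1 in 20.

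Female-biased genes fell in hepatocyte-like nuclei of FPC females, 8 of 29 past the threshold. Male nuclei under the female FPC hashtag were excluded as the source, because the 4 Y-linked genes stood at a median of 4.51% (2.56% to 6.69%) of their level in FPC males, far below the share of male nuclei that such a fall would need. Free RNA of the pool would have raised male-biased genes in these females, and instead 5 of them were lower and 1 higher when adjusted over the list alone. In sums thinned to the smallest mouse the 8 genes had a median log2 change of -2.47 against -2.46 without thinning, and 7 still passed, so these 7 calls did not need the larger sums. Thinning draws at random from each sum and keeps the expected log2 change, so it could not exclude an effect of depth. Nor did it make UMIs per nucleus equal between the diets. Hepatocyte nuclei left without a hashtag by HTODemux and assigned by the other caller are argued against, since over all nuclei of that caller the median of the 8 genes was -2.40 and all 8 still passed. Neither caller gave 1 hashtag to 23.1% of hepatocyte-like nuclei, and their loss stays open. An effect of the diet on female-biased transcription may remain as a hypothesis.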

How the results depend on the processing

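The alternatives named as chosen after seeing the data were MULTIseqDemux assignment of all nuclei, removal of nuclei with transcripts of the other sex, classes from clusters at resolution 1.0, a minimum of 10 macrophage-like nuclei and, for shares, Scrublet doublets kept; the others were set before, though the MULTIseqDemux fits of macrophage-like genes with a lone chow female were allowed only after. Over 6812 alternative values of 341 results of named genes, 6039 (88.7%) kept their direction and their side of the threshold, 547 (8.03%) kept their direction and lost the call, 208 (3.05%) gained one and 18 turned direction, none of them called. Results that were not called in the main fit are part of the 6812 and could not lose a call. Among results called in the main fit the share lost was therefore higher than 8.03%. Sums thinned to the smallest mouse, 16920 UMIs in macrophage-like nuclei, called 46 of 351 genes tested there instead of 81 of 2454, so lower depth left fewer genes past the count filter. In simulated hepatocyte-like, stellate-like and endothelial-like sums 14.9% to 23.9% of genes changed 1.5-fold were called, and macrophage-like sums were not simulated. Where no reason is given, the cause was not tested.

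Without the pool term 192 genes were called in females, 65 in males, 466 by sex on the FPC diet, 0 for the interaction (edgeR; 1408 at an unadjusted p under 0.05), 0 in stellate-like (152) and 14 in macrophage-like nuclei. DESeq2 called 310 in males, 345 by sex on chow, 105 for the interaction and 1 each in endothelial-like and stellate-like nuclei; its split into higher and lower genes was 319 and 175 in females and 378 and 259 averaged over the sexes. Without a count filter, which tested more genes, 1376 were called in females, 787 in males, 1441 averaged, 679 by sex on chow, 1895 by sex on the FPC diet, 511 for the interaction and 4 in stellate-like nuclei. With Scrublet doublets kept 3 were called for the interaction, 6 in endothelial-like and 45 in macrophage-like nuclei. MULTIseqDemux gave 7 in endothelial-like and 9 in stellate-like nuclei, and 2 for the interaction when applied to all nuclei. In macrophage-like nuclei MULTIseqDemux gave 50 and, over all nuclei, 21, and a minimum of 10 nuclei gave 38. Thinned sums gave 1 in endothelial-like and 46 in macrophage-like nuclei, clusters at resolution 1.0 gave 8 in stellate-like and 0 in macrophage-like nuclei (36 at an unadjusted p under 0.05, with 552 genes tested instead of 2454), and macrophage-like counts were 39 with at least 1000 genes per nucleus, 48 after stricter doublet removal and 30 without nuclei of the other sex. Of 55 gene list calls, 1 held with an estimated correlation.

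Share changes are log2 values. The endothelial-like diet effect, 0.02 and not called, turned to -0.18 with MULTIseqDemux, -0.0766 with Scrublet doublets kept, -0.14 among non-hepatocyte nuclei and -0.0277 in the permutation, the T or NK cell-like effect to -0.0118 at Leiden 1.0 and the stellate-like effect to 0.15 over all MULTIseqDemux nuclei, none called. The macrophage-like rise was 1.28 at Leiden 1.0 and 1.81 over all MULTIseqDemux nuclei, not passing, 3.04 in females over all MULTIseqDemux nuclei, not passing, and 1.15 in males with Scrublet doublets kept, passing; over its edgeR alternatives the adjusted p of the averaged rise ran from 5.09e-07 to 0.272. It was 1.87 in the permutation, where no single class could pass over 7 classes. Of the sex differences on the FPC diet that no longer passed, the macrophage-like one was 1.79 over all MULTIseqDemux nuclei and 0.66 among non-hepatocyte nuclei, the endothelial-like one 0.11 there, the stellate-like one 1.95 over all MULTIseqDemux nuclei and -0.20 among non-hepatocyte nuclei, a turned direction, and the hepatocyte-like one -0.16 with MULTIseqDemux and -0.29 over all its nuclei.

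Leaving out 1 mouse at a time left a lone mouse in its group, assumed to vary like the other groups. Counts then ranged from 10 to 536 in females, 13 to 210 in males, 77 to 466 averaged, 67 to 293 by sex on chow, 44 to 715 by sex on the FPC diet, 0 to 11 for the interaction, 0 to 3 in endothelial-like, 5 to 14 in stellate-like and 24 to 147 in macrophage-like nuclei. The correlation between the sexes ranged from 0.202 to 0.329. Diet effects on shares ranged from 1.49 to 2.17 (macrophage-like), 2.18 to 3.39 (macrophage-like, females), -0.32 to 0.27 (endothelial-like), -0.48 to 0.84 (T or NK cell-like) and -4.81 to -1.75 (mesothelial-like, the former without the mouse that held all 5 such nuclei of the FPC mice), and sex differences on the FPC diet from 1.38 to 2.59 (macrophage-like), 0.76 to 1.93 (endothelial-like), 0.70 to 1.42 (stellate-like) and -0.17 to -0.13 (hepatocyte-like). Named genes that turned direction without a mouse, none called, ranged as follows: mt-Nd5 from -0.32 to 0.0323 and mt-Nd3 from -0.36 to 0.0690 by sex on the FPC diet, Fgb from -0.77 to 0.12 for the interaction, Cdkn1a from -1.39 to 0.24 by sex on chow, Kif15 from -0.0341 to 0.91 in males and Slc40a1 from -0.45 to 0.18 in macrophage-like nuclei. Slc40a1 was also 0.13 without a count filter, 0.0819 after stricter doublet removal, 0.15 without nuclei of the other sex, 0.27 at resolution 1.0, 0.0107 over all MULTIseqDemux nuclei and 0.37 with a minimum of 10 nuclei, against -0.18. Over all MULTIseqDemux nuclei Soat1 by sex on chow turned to -0.0294 and Gata4 in endothelial-like nuclei to 0.0184.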

Other observations

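Of the tests in this part, those of endothelial markers, of secreted transcripts, over all nuclei of the other caller and of other splits of the mice were chosen only after the results were seen. Stricter doublet removal and shares among non-hepatocyte nuclei were alternatives set before, and their use as tests of an explanation was chosen after.

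In stellate-like nuclei of females 47 genes changed with the diet, 36 higher and 11 lower (edgeR; 278 at an unadjusted p under 0.05), and 2 changed in males. The basement membrane collagen Col4a1 rose from 79.5 ± 32.8 to 398 ± 23.8 CPM in females (2.28 ± 0.40, SE, n = 2 per group), and Col4a2 (2.50 ± 0.59), Col14a1 (1.20 ± 0.21), Tgfbi (1.39 ± 0.33) and Sparc (1.21 ± 0.34) rose with it. On the FPC diet 23 genes differed by sex, 16 higher in females, Col4a1 among them (1.53 ± 0.43, adjusted p = 0.0424). Of 14 matrix genes 1 was higher in FPC females than in FPC males, and 7 when adjusted over the list alone (median 0.70, adjusted p = 1.48e-05, and adjusted p = 0.246 with an estimated correlation). In endothelial-like nuclei the Kupffer cell list rose with Cd5l, 1 of its 4 measured genes (median 0.63, adjusted p = 0.0136, and adjusted p = 0.459 with an estimated correlation). These results were chosen after their values were seen, and the genes in 1 sex or on 1 diet were not run under the alternatives. Both lists passed without the pool term (adjusted p = 1.10e-05 and 0.0149) and did not with an estimated correlation.

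The diet split of the 8 mice was compared with the other splits into 4 and 4 that took 2 mice of each pool per side, 18 splits in all. The model held the split with sex and pool as terms wherever they differed from it, and its counts differ from those of the model with 4 groups. These 18 splits are too few for a share under 0.05. In hepatocyte-like nuclei the diet called 242 genes, as many in 1 of the 18, and the highest other count, 218, was the split by sex. In macrophage-like nuclei it called 80, as many in 1 of 18, with 1 gene as the highest other count. In endothelial-like nuclei it called 2, as many in 3 of 18, with 3 as the highest other count, and in stellate-like nuclei 11, as many in 2 of 18, with 12 as the highest other. The other 17 of all 35 splits are unbalanced over the pools. Among them the split by pool called 24 genes in endothelial-like and 18 in stellate-like nuclei, against the 2 and 11 of the diet with the pool as a term. It called 0 in hepatocyte-like and macrophage-like nuclei (edgeR; 1337 and 104 at an unadjusted p under 0.05). The count of 24 is several times that of the diet, which points to a structure by pool in endothelial-like sums. The reported model holds the pool as a term.

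The macrophage-like share rose on the FPC diet by a log2 value of 1.79, and the call ended without the pool 2 or pool 3 FPC female (1.83 and 1.88) or the pool 2 FPC male (1.49). A lower share of hepatocyte nuclei is argued against, since the rise was 1.74 among non-hepatocyte nuclei. After stricter doublet removal it was 1.65 and still passed, so the nuclei with the highest doublet scores did not account for it. Other doublets stay open, since Scrublet called only 44.1% and 45.3% of barcodes with more than 1 hashtag. At resolution 1.0, where the call was lost, 128 nuclei of the second round were macrophage-like (median 2520.5 UMIs). An unnamed cluster there held 121 deeper nuclei (median 5974 UMIs), 38.8% of them from the pool 2 FPC female. Nuclei lost to the hashtag assignment cannot be told apart from a rise, because over all nuclei assigned by the other caller it was 1.81 and did not pass (adjusted p = 0.272, 5.09e-07 to 0.272 over its edgeR alternatives). More macrophages in the liver on the diet may be the source and stays open, untested.

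Gene levels in the macrophage-like class changed on the FPC diet. RNA or nuclei of endothelial cells in the class may be a source, as all 10 measured endothelial markers were above 0 with a median of 1.38 ± 0.19 (SE over markers), and Stab2 (1.48 ± 0.28), Ptprb (1.46 ± 0.29) and Adgrl4 (1.76 ± 0.43) passed. Less free hepatocyte RNA per macrophage-like nucleus is a candidate explanation of the falls, as all 15 secreted hepatocyte transcripts were below 0 with a median of -0.75 and an SD of 0.152. A response of macrophages to the diet stays open as well, and these tests do not separate it from either source.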
